A study of Drosophila melanogaster with 4 samples.

How the data were processed

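Fiber-seq was done on Drosophila S2-DRSC cells (written S2-DSRC in the labels). Per the labels, nuclei were isolated with a mild detergent and treated with the m6A methyltransferase Hia5 for 10 min at 37 °C, at 500 U or 20 U, and DNA was sheared and sequenced on PacBio HiFi libraries made without PCR. The controls are deproteinized DNA treated with 500 U of Hia5 and genomic DNA without Hia5. Each of the 4 conditions has 1 library, and groups were taken from the sample titles. The library code of each control's file stands in the description of the other control, so the controls are named here only as they are labelled, and no result rests on which is which.

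For each library, a deposited list gives the start and end of every fiber in bp and, as its other value, a hole number of the sequencing chip. For the 500 U library, the authors also deposited a track of m6A calls, in which each fiber has a count of marked positions, the positions themselves and a score. The meaning of the score is not stated in the deposited files. Its values are whole numbers of at least 10 with a median of 13. Coordinates are on dm6, the build named in the submitters' processing notes. The aligner, the m6A caller and the choice of fibers for the track are not given in the sources used here. The track holds 555955 of 2776086 listed fibers. On each of these, the first and last marked positions are the fiber's ends, so they were dropped, along with 7334 marks that repeat an end, which left 347216200 calls. There were 407 fibers without a call. Fiber starts in the track are 1 bp lower than in the list, so positions are uncertain by 1 bp. Calls at a reference A or T could not be counted, since no genome sequence was used here, and m6A is given per kb of fiber with no correction for A/T content.

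Genes came from the Release 6 gene table of the same build, in which strand is not given and each gene has a single start and end. The planned transcription start was therefore replaced by both gene ends, and 13922 protein-coding genes on arms 2L, 2R, 3L, 3R and X and on chromosome 4 were used. A footprint was a gap of at least 85 bp between neighbouring m6A calls of a fiber, and a patch was the stretch of at least 150 bp between neighbouring footprints. A fiber was open at a gene end when a patch covered at least 100 bp of the 200 bp window from 150 bp outside to 50 bp inside the gene. Fibers had to span the window and 500 bp on both sides, and genes needed 20 such fibers. Fibers were split by the parity of the hole number. In each part the more open end of the gene was chosen, and its share was measured in the other part. Counting error in the choice therefore does not raise the share. A gene is still scored at the more open of its ends, while background windows are scored singly, which can raise genes over background. Both parts chose the same end in 83.1% of genes.

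Background was the pooled share at 20000 random windows of 200 bp at least 2 kb from any gene end (seed 1), of which 16081 had enough fibers. Each gene's share was compared with it by an exact binomial test, two-sided, with Benjamini-Hochberg adjustment over all 12433 tested genes and a threshold of 0.05. Where the parts chose different ends, the measured share is lowered by construction, as in 451 of 598 genes with a share below background. After these results were seen, a gene was called below background only where both ends, each over all its fibers, were below, which held for 225 genes. Genes above background kept the original call, and in 176 of them the parts had chosen different ends. The share printed for a single gene is that of the chosen end where the parts chose the same one. Otherwise it pools the window passages over both ends, in which a fiber that spans both ends enters at each. Intervals are exact Clopper-Pearson intervals at 95%. The number of fibers per gene (median 40, quartiles 33 and 47) sets the precision.

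The 17 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists are cytosolic ribosomal proteins, mitochondrial respiration, proteasome, DNA replication, heat shock, hemocyte and S2, antimicrobial peptides and recognition, neuronal, muscle, chemoreceptors, cuticle proteins, Hox genes, developmental transcription factors (Polycomb targets), ecdysone response, testis and germline, yolk and chorion, and replication-dependent histones. Listed names were matched through symbols and synonyms, and 3 names of the testis list were not matched. Each list's median cross-fitted share was placed among 10000 random lists of the same size matched on quintile of fiber coverage, and the outer 2.5% on each side was taken as the limit. Named genes are the 2 with the highest and the 1 with the lowest share in each list, 6 fixed genes (Act5C, RpL32, Hsp83, Gapdh1, Hml and elav), the 10 most open genes with at least 40 fibers and a symbol other than a bare CG or CR number, and the 5 pairs with the smallest adjusted p. Ties went to the higher number of fibers. The sets without another gene's end within 1 kb and the neighbours named beside genes were added after the values were seen. Neighbours further than 200 bp are not named for most genes, as at mad2 (245 bp from an end of vn) and RpL32 (309 bp from an end of CG7943). An end without a named neighbour is therefore not necessarily far from other genes.

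Centromere-proximal sequence was 2L from 22 Mb, 2R up to 5.5 Mb, 3L from 23 Mb, 3R up to 4 Mb and X from 22 Mb, compared with the rest of each arm by an exact sign-flip test over the 5 arms. Footprint lengths were taken from 85 to 220 bp and centre distances from 120 to 300 bp, and modes were smoothed over 11 bp. Gene bodies left out 500 bp at each end. Pairs of distinct gene ends above background with open shares of 10% to 90%, 500 bp to 10 kb apart and spanned by 20 fibers, were tested for joint opening. The Mantel-Haenszel odds ratio was taken over pairs with fibers in 5 strata of their m6A rate outside both windows and 500 bp around them, with 100 permutations within pair and stratum and intervals from resampling pairs 1000 times. Pairs share gene ends and fibers, so the intervals may be too narrow. Random windows were treated in the same way, except that they did not have to be above background.

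The method was tested on simulated data. In 400 simulated windows the open share was recovered with a median absolute error of 4.0 percentage points, a simulated repeat of 180 bp was recovered as 180 bp, and odds ratios of 1 and 4 were recovered as 0.99 and 3.57. All simulated fibers had the same methylation rate and length. The recovered odds ratios therefore do not show how well the strata remove differences in m6A between real fibers. Closed windows were simulated as protected apart from a short gap. Real footprints had a mode of 93 bp, near the cut of 85 bp, so the error of real shares can be larger. In a simulation of the gene test, 0.1% of 5000 unchanged genes were called, and 72.5% of 200 genes with 70% against 40% open on 40 fibers. The unchanged genes were drawn at exactly the share they were tested against. Real random windows vary more, with 15.1% called above background and 13.7% below, so the 0.1% is not the rate of false calls in these data. A draft of the strata that left only the windows out recovered an odds ratio of 1 as less than 1, and the 500 bp margin was added for that reason, before the real odds ratios were seen.

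Alternatives covered the footprint gap, the patch length, the number of fibers, fiber length and m6A rate, the limits of proximal sequence (moved 1 Mb towards the telomere), the background, the strata and the share limits of pairs. Further ones were chosen after seeing the data, and the closing section names these and those not run. Matching on A/T content and the comparison of core promoter elements need the genome sequence and were not analysed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0 were used.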

Results

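The series measured accessible DNA on single chromatin fibers of Drosophila S2-DRSC cells, a cultured line of hemocyte-like character derived from embryos. Nuclei were treated with Hia5, an enzyme that methylates adenines not covered by nucleosomes or other proteins, and the methylated adenines (m6A) were read on single DNA molecules by long-read sequencing without PCR. There were 4 libraries, 1 per condition, so no condition had a replicate and no test between conditions was possible. The library from nuclei treated with 500 U of Hia5 held 2776086 fibers (26.6 Gb, median length 9440 bp, mean coverage 198 on the large arms and chromosome 4). Nuclei treated with 20 U gave 498010 fibers (0.740 Gb, median 1478 bp, coverage 5.47). The library labelled deproteinized DNA with Hia5 held 442375 fibers (0.447 Gb, median 1180 bp, coverage 3.29), and the library labelled genomic DNA without Hia5 held 396844 fibers (2.05 Gb, median 5098 bp, coverage 15.2). Each control's file carries the library code that the labels give to the other control, so which of them each file holds is open. Positions of m6A were used for 555955 of the fibers treated with 500 U (20.0%), which covered the arms and chromosome 4 at a mean of 42.3. All shares of open fibers below are therefore from the fibers of 1 library, and their exact 95% intervals cover counting error only.

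The question of how evenly the libraries sampled the genome was addressed with fiber positions alone. Chromosome X was covered at 0.666 of the arm mean in the 500 U library, at 0.761 in the 20 U library, and at 0.720 and 0.661 in the libraries labelled deproteinized and genomic DNA. Chromosome 4 stood at 0.753 of the arm mean with 500 U and at 0.588 in the library labelled genomic DNA, but at 1.03 and 1.06 in the other pair. Mitochondrial DNA made up 0.0812% of fibers with 500 U (95% interval 0.0779% to 0.0846%) and 0.635% with 20 U (0.613% to 0.658%). It made up 0.694% in the library labelled deproteinized DNA (0.670% to 0.719%) and 0.00378% in that labelled genomic DNA, where 15 fibers were seen (0.00212% to 0.00623%). The same pairing appeared in the coverage of 1336 bins of 100 kb. Across bins, which are not independent replicates, Spearman's rho was 0.855 between the 500 U library and that labelled genomic DNA, and 0.860 between the 20 U library and that labelled deproteinized DNA. The remaining pairs of libraries had rho between 0.661 and 0.773. The pairs also differed in fiber length and in the range of hole numbers on the sequencing chip, so condition and sequencing format cannot be told apart.

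Fiber ends lay slightly more often beside gene ends than 2 to 5 kb away in each library. The ratio of end densities was 1.10 with 500 U (95% interval 1.10 to 1.11), 1.12 with 20 U (1.10 to 1.13), 1.05 in the library labelled deproteinized DNA (1.04 to 1.07) and 1.10 in that labelled genomic DNA (1.09 to 1.12). Coverage itself was higher beside gene ends with 500 U (ratio 1.05) and in the library labelled genomic DNA (1.05), but not with 20 U (0.992) or in the library labelled deproteinized DNA (0.985), and the end densities were not corrected for it. The difference between nuclei and controls was not tested, for lack of replicates.

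On the large arms and chromosome 4, fibers of the 500 U library carried 61.1 m6A calls per kb (SD over the 5 large arms 0.781). The median fiber had 64.3 calls per kb, with quartiles of 50.5 and 77.2 over 553378 fibers. Chromosome 4, which is largely heterochromatic, had 61.4 calls per kb, and the Y chromosome, which is wholly heterochromatic, had 63.6. Among all listed fibers of this library, Y was covered at 0.112 of the arm mean and X at 0.666. The Y value may therefore not stand for the whole chromosome, and none of these values is corrected for A/T content. Mitochondrial DNA, which has no nucleosomes, carried only 8.08 per kb. Centromere-proximal sequence, rich in heterochromatin, had fewer calls than distal sequence on 5 of 5 arms, with a mean difference of -1.69 per kb (SD 1.18). On 3L, proximal sequence had 57.2 calls per kb and distal sequence 60.9, and on X the values were 59.0 and 60.6. The exact sign-flip test over 5 arms, two-sided, gave p = 0.063, the smallest value that 5 arms allow, so the threshold could not be reached. With the limits of proximal sequence moved 1 Mb towards the telomere the difference was -0.933 per kb (SD 1.02), again lower on 5 of 5 arms. Without the 10% of fibers with the lowest and the 10% with the highest m6A the difference was -0.043 per kb, with 3 of 5 arms lower in proximal sequence and an exact p of 0.75. This trim is by the measured quantity itself and removes more proximal fibers at the low end (16.4% of proximal and 9.50% of distal fibers on 3L), so a smaller difference follows in part by construction.

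At the more open end of 12433 protein-coding genes the m6A signal rose at the end itself and then oscillated into the gene. This end was chosen in one part of the fibers and measured in the rest. The signal there reached 92.3 calls per kb at 4 bp inside the gene. It fell to 55.2 at 131 bp, rose again to 78.5 at 219 bp and fell to 61.4 at 326 bp. Genes above background had a higher maximum of 120 calls per kb at -50 bp, outside the gene, and a deeper minimum of 48.7 at 133 bp. Part of this maximum follows from the selection, since these genes were called from m6A in the window from 150 bp outside to 50 bp inside the gene. The 79 genes for cytosolic ribosomal proteins went further, from 136 calls per kb at -62 bp to 34.5 at 150 bp. The 158 chemoreceptor genes had no peak of this kind, with at most 70.4 calls per kb near the gene end and a minimum of 57.9 at 163 bp. The less open end had no such peak, and from 300 bp outside to 50 bp inside the gene its highest value was 65.7 calls per kb. Choosing the more open end raises its signal in the window and lowers that of the other end, so part of this contrast follows by construction. Gene strand was not used here, so a more open end is not necessarily a transcription start.

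**Figure D1:**
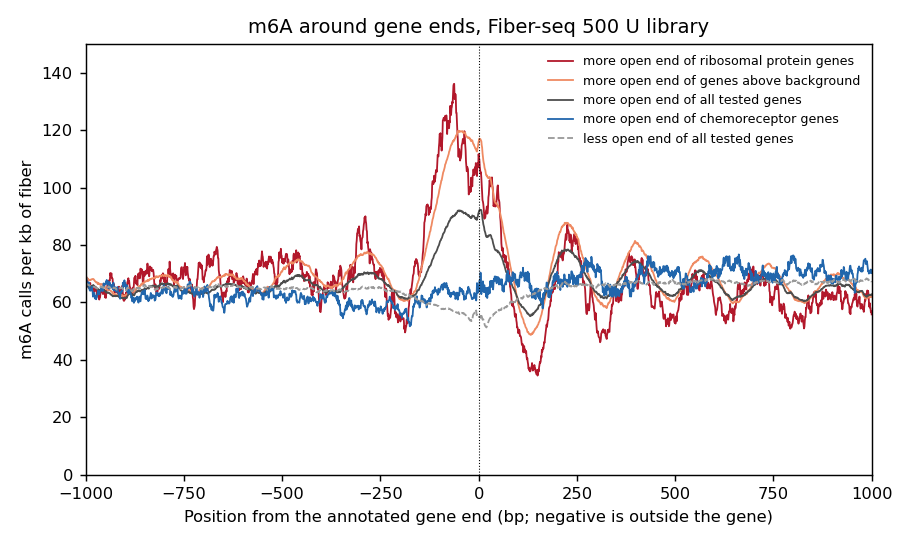
m6A calls per kb of fiber (vertical axis) by position from the gene end in bp (horizontal axis, positive inside the gene) in the 500 U library, smoothed over 11 bp, for the gene groups named in the legend. Genes above background peak at 120 calls per kb just outside the gene and ribosomal protein genes at 136, with a minimum about 130 to 150 bp inside.

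A fiber was called open at a gene end when an accessible patch of at least 150 bp covered at least 100 bp of a window reaching from 150 bp outside to 50 bp inside the gene. Of 12433 genes tested, 6791 (54.6%) were open on more fibers than random DNA at least 2 kb from any gene end, where 41.1% of fibers were open by this definition. Protected stretches shorter than 85 bp do not end a patch, so an open fiber is not necessarily free of nucleosomes there. On the arms and chromosome 4, footprints numbered 18195867 with the gap of 85 bp and 25320943 with a gap of 60 bp. The level of the open share therefore depends on this cut. At 225 genes (1.81%) both ends were open on fewer fibers than background, and 5417 genes were not called. The median gene was open on 62.9% of its fibers, with quartiles of 43.2% and 89.7%, and 3057 genes (24.6%) were open on at least 90%. Each test was an exact binomial test over the fibers of 1 library, two-sided, adjusted over all genes, with a median of 40 fibers per gene. By the same test 15.1% of the random windows themselves stood above background and 13.7% below. A random window is scored alone and a gene at the more open of its ends, so these shares are not like for like. Counted singly, 7697 of 24230 distinct gene ends were above background and 2936 below. Most genes had another gene's end nearby, and among the 1957 genes with none within 1 kb, a set taken after the values were seen, 521 (26.6%) were above and the median was 46.5%.

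Most genes with an open end had only 1 such end. Of 11794 genes with both ends tested, 5544 had exactly 1 end above background, 996 had both and 5254 had none. Genes on chromosome X had a median share of 68.1% (994 genes), against 59.0% on 2L, 65.4% on 2R, 62.0% on 3L, 63.4% on 3R and 60% on chromosome 4 (71 genes). The 147 genes in centromere-proximal sequence had a median of 55.6%, with 47.6% of them above background. For the 12215 distal genes these values were 63.0% and 54.7%. These differences between chromosomes and regions were not tested.

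Genes of basic cell growth were the most open. Cytosolic ribosomal protein genes had a median open share of 89.5%, and 71 of 79 tested genes were above background (71 when adjusted over the list alone). None of 10000 random lists matched on coverage had a median as high (percentile 100). RpS29 (Dmel_CG8495) and RpS28a were open on 41 of 41 fibers each (100%, 95% interval 91.4% to 100%), at ends 99 bp from an end of topi and 194 bp from an end of Axn, while RpL10Aa was open on 25% of 100 window passages over both ends (16.9% to 34.7%) and was not called. Proteasome genes, for the main protease of the cell, had a median of 91.3% with 26 of 30 above background (26 adjusted over the list alone, percentile 99.95). Rpn1, of the regulatory particle, was open on 45 of 45 fibers and Prosbeta1, of the catalytic core, on 40 of 40, at an end 121 bp from an end of Rrp42, against 30% of 40 at Rpn13, a ubiquitin receptor. DNA replication genes had a median of 91.1% with 20 of 23 above background (20 adjusted over the list alone, percentile 99.85). PolE1, the catalytic subunit of DNA polymerase epsilon, was open on 37 of 37 fibers and Orc4, of the origin recognition complex, on 30 of 30. At geminin, an inhibitor of replication licensing, the share was 34.1% at one end and 19.6% at the other, and the gene was not called. Among genes with at least 40 fibers the percentile of the proteasome list was 95.9, outside the highest 2.5% of random lists.

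Genes of mitochondrial respiration had a median of 77.4%, with 49 of 76 above background (49 adjusted over the list alone) and a percentile of 98.7. ATPsynF and ATPsynO, subunits of ATP synthase, were open on 45 of 45 and 33 of 33 fibers, ATPsynF at an end 126 bp from an end of CG3548. ND-49L, related to a subunit of complex I, was open on 24.3% of 37 fibers (11.8% to 41.2%) and not called. The list's position held in some settings and not in others. The percentile was 99.8 with a footprint gap of 75 bp, 99.3 with patches of at least 120 bp and 99.97 when lists were matched also on gene length. Among its 13 members without another gene's end within 1 kb the median was 43.9% and the percentile 32.1, and with patches of at least 200 bp the percentile was 83.7. The list also fell within the range of random lists in several further settings, given in the closing section.

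Genes for sensory receptors and for the outer cuticle, tissues that the line does not form, were among the least open. The median open share of chemoreceptor genes was 45.7%, below that of every one of 10000 random lists (percentile 0), with 35 of 158 above background and 2 below (21 and 1 adjusted over the list alone). Gr59f, a gustatory receptor, was open on 90.3% of 31 fibers, but its open end lies 139 bp from an end of AIMP3, and the open end of Ir25a, an olfactory co-receptor open on 89.1% of 55 fibers, lies 153 bp from an end of Fnta. Gr93d was open on 20% of 30 fibers (7.71% to 38.6%), at an end 52 bp from an end of asRNA:CR44087. Cuticle protein genes also had a median of 45.7% and a percentile of 0, with 20 of 109 above and 1 below (12 and 1 adjusted over the list alone). Lcp9 was open on 90.6% of 32 fibers, at an end 8 bp from an end of asRNA:CR44067, and Cpr12A on 76.2% of 21, while TwdlS was below background at 16.7% of 48 (7.48% to 30.2%). Among members without another gene's end within 1 kb, 45 chemoreceptor genes had a median of 48% (percentile 68.0) and 36 cuticle genes one of 46.9% (percentile 55.5), so there neither list was lower than other genes.

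Testis and germline genes had a median of 45% and a percentile of 0.32, with 8 of 27 above and 1 below (8 and 1 adjusted over the list alone). The gene topi, a regulator of spermatocyte transcription, was open on 41 of 41 fibers, at an end 99 bp from that of RpS29, and ocn on 95.1% of 41, at an end 133 bp from an end of ZIPIC. At aly, another regulator of spermatocyte transcription with no gene end within 1 kb of its more open end, 15.2% of 33 fibers were open (5.11% to 31.9%), below background. Among 6 members without another gene's end within 1 kb the list's percentile was 9.43, and among genes with at least 40 fibers it was 11.8.

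**Figure D2:**
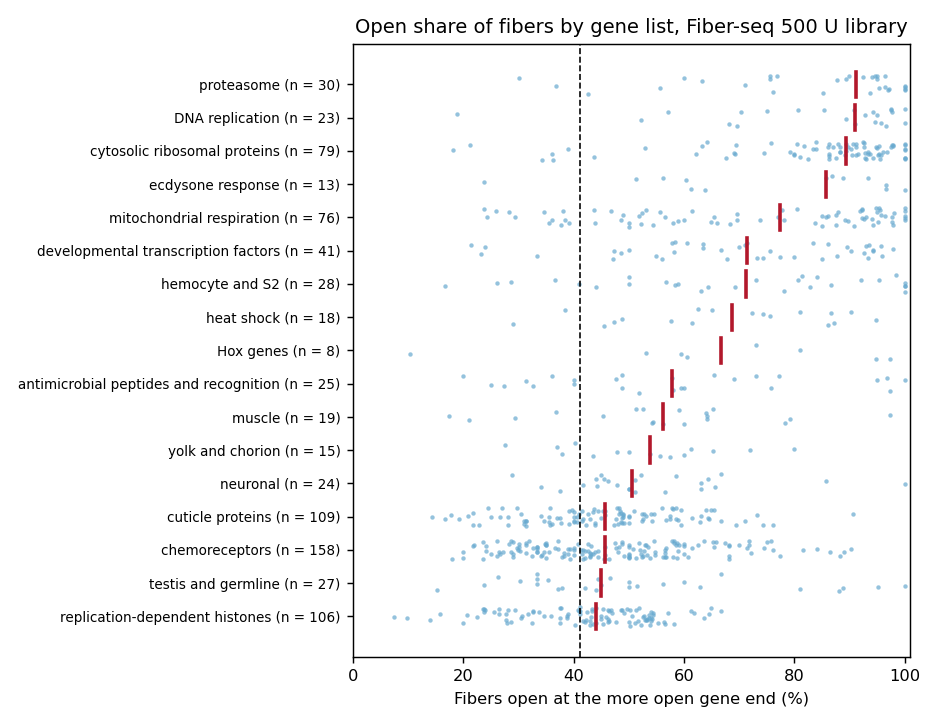
Open share in percent of fibers (horizontal axis) of the genes of each fixed list (vertical axis) in the 500 U library. Points are single genes by their cross-fitted share, red bars mark list medians and the dashed line is the background of 41.1%. Proteasome and DNA replication genes have medians above 91%, chemoreceptor and cuticle genes medians of 45.7%.

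Lists for neurons and muscle, cell types that the line is not, lay within the range of random lists. Neuronal genes had a median of 50.5% and a percentile of 7.03, with 7 of 24 above background (6 adjusted over the list alone). Syx1A, a syntaxin of membrane fusion, was open on 34 of 34 fibers and the calcium channel gene cac on 85.7% of 21, at an end 67 bp from an end of gd. The gene nSyb, for a vesicle protein of synapses, was open on 28.8% of 52 (17.1% to 43.1%), at an end 190 bp from an end of Mettl2. With a footprint gap of 100 bp the percentile of the neuronal list was 1.56, and matched also on gene length it was 1.41, but for its 6 members without another gene's end within 1 kb it was 64.3 (median 49.2%). Muscle genes had a median of 56.1% and a percentile of 22.5, with 9 of 19 above and 1 below (9 and 0 adjusted over the list alone). Mef2, a transcription factor of muscle that acts in other tissues too, was open on 97.3% of 37 fibers and the myosin light chain gene Mlc1 on 79.3% of 29, at an end 82 bp from an end of tau. The open end of Mef2 lies 261 bp from an end of Pdrg1. TpnC41C, a troponin C, was below background with 25% at one end and 19.0% at the other. Yolk and chorion genes, active in the ovary and fat body, had a median of 53.8% and a percentile of 20.7, with 6 of 15 above (6 adjusted over the list alone). The chorion genes Cp38 and Cp7Fb were open on 80% of 20 and 72% of 25 fibers, and psd on 32.2% of 59 window passages over both ends.

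Genes of hemocytes and of immune recognition were mixed. The hemocyte and S2 list had a median of 71.2% and a percentile of 81.9, with 18 of 28 above and 1 below (19 and 1 adjusted over the list alone). The scavenger receptor gene crq was open on 47 of 47 fibers, at an end 84 bp from an end of shv, and ush, a cofactor of GATA factors in blood cell formation, on 59 of 59, at an end 39 bp from an end of lwr. He, for the hemocyte surface protein Hemese, was below background at 16.7% of 36 fibers (6.37% to 32.8%), at an end 77 bp from an end of NimB5. Antimicrobial peptide and recognition genes had a median of 57.9% and a percentile of 25.2, with 10 of 25 above (10 adjusted over the list alone). The signalling genes imd and Rel were open on 35 of 35 and 97.4% of 39 fibers, and PGRP-SB1, for a secreted peptidoglycan recognition protein, on 20% of 30, not called, at an end 11 bp from an end of PGRP-SB2. Heat shock genes had a median of 68.7% and a percentile of 61.4, with 12 of 18 above (12 adjusted over the list alone). Hsp68 was open on 94.9% of 39 fibers and DnaJ-1, a co-chaperone gene, on 90.3% of 31, while Hsp22, of the small heat shock proteins, had 35.9% at one end and 35% at the other.

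Regulators of development were mostly above background, though their lists lay within the range of random lists. Hox genes had a median of 66.7% and a percentile of 58.2, with 6 of 8 above background (6 adjusted over the list alone). The genes lab and Scr, which set head and thorax identity, were open on 97.4% of 38 and 94.9% of 39 fibers, while Ubx, which acts further back, had 29.2% at one end and 28.2% at the other and was not called. Developmental transcription factor genes, many of them targets of Polycomb repression, had a median of 71.4% and a percentile of 85.4, with 29 of 41 above (30 above and 1 below adjusted over the list alone). The zinc finger genes salr and opa were open on 97.9% of 47 and 95.8% of 24 fibers, and inv, a homeobox gene, on 21.4% of 28 (8.30% to 41.0%). Among the 32 members without another gene's end within 1 kb the median was 76.6%, above every random list, with 23 above background. Ecdysone response genes had a median of 85.7% and a percentile of 94.7, with 11 of 13 above (11 above and 1 below adjusted over the list alone). Eip63E, a cyclin-dependent kinase gene, was open on 82 of 82 fibers and Hr39, a nuclear receptor gene, on 96.6% of 59, against 23.7% of 38 at Ldh, for lactate dehydrogenase. With patches of at least 200 bp the percentile was 98.4 for the developmental factors and 99.3 for the ecdysone list. In the other direction, it was 54.4 for the developmental factors matched also on gene length and 63.2 for the ecdysone list among genes with at least 40 fibers.

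The replication-dependent histone genes had a median of 44.1% and a percentile of 0, with 32 of 106 above and 18 below (32 and 19 adjusted over the list alone). They stand in a repeated array where the place of a fiber is uncertain, so single copies cannot be read with confidence. Matched also on gene length the percentile was 2.51, just inside the limit of 2.5. The highest shares were 66.7% of 24 fibers at His3:CG33833 and 64.9% of 37 at His3:CG33803, and the lowest was 14.1% of 85 window passages at His1:CG33813.

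Among genes fixed in advance, the actin gene Act5C (Dmel_CG4027, X from 5900861 to 5905399) was open on 97.6% of 41 fibers (95% interval 87.1% to 99.9%, exact binomial test, adjusted p = 1.14e-13). RpL32 was open on 83.3% of 24 fibers (62.6% to 95.3%), the chaperone gene Hsp83 on 75.7% of 37 (58.8% to 88.2%) and the glycolysis gene Gapdh1 on 72.3% of 47 (57.4% to 84.4%), and each was above background. The open end of Hsp83 lies 14 bp from an end of CG14966. Hml, for the hemocyte protein hemolectin, was open on 44.1% of 59 fibers (31.2% to 57.6%) and did not differ detectably from background (exact binomial test, adjusted p = 0.766). The neuronal gene elav was open on 11 of 11 fibers at its upper end, too few to be tested, and this end lies at an end of lncRNA:enrr.

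Of genes with at least 40 fibers, 185 were open on every fiber, among them the top 10. The order of these 10 follows from fiber number. Eip63E (3L from 3515751 to 3610521) led with 82 fibers and an interval of 95.6% to 100%. It was followed by Pld, a phospholipase, and caly, a deubiquitinase of the Polycomb group, with 60 fibers each, by ush with 59 and by the spindle checkpoint gene mad2 with 58. Elp2, of the Elongator complex, had 57 fibers, and Ndf, a nucleosome destabilising factor, had 56. Bicra, Creld and Cul5 had 55 each, and the open ends of Bicra and Cul5 lie 65 bp apart, while that of caly lies 51 bp from an end of CG44242.

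Accessible patches at gene ends were narrower than those at background windows with the footprint gap of 85 bp, a direction that turned with a larger gap. On open fibers at gene ends above background the median patch measured 460 bp, with quartiles of 267 and 796 bp over 258769 fiber windows. Patches at background windows had a median of 520 bp, with quartiles of 294 and 940 bp. A window placed at random meets long patches more often than short ones, so a greater width at background can follow in part by construction. The width depends on the gap that counts as a footprint, with medians of 268 bp at gene ends and 316 bp at background for a gap of 60 bp, and 347 and 444 bp for 75 bp. For a gap of 100 bp they were 841 and 834 bp, so the sign of the difference depends on this choice. With the 60 bp gap the median share of open fibers was 40% at genes and 19.7% at background.

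Neighbouring footprints on single fibers had nearly the same median distance in each part of the nuclear genome that was compared. The protected stretches between m6A calls had a median length of 112 bp and a mode of 93 bp over 18195867 footprints of 85 to 220 bp. Neighbouring footprints lay a median of 177 bp apart from centre to centre, with a mode of 175 bp. Bodies of genes above background had a median distance of 176 bp and bodies of other genes one of 178 bp, shorter by 2 bp on average with the same direction on 5 of 5 arms. The exact sign-flip test gave p = 0.063, the smallest value possible. DNA between genes had 178 bp, chromosome 4 had 178 bp and the Y chromosome had 177 bp. Proximal sequence differed from distal sequence by 0.6 bp (exact p = 0.25 over 5 arms).

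**Figure D3:**
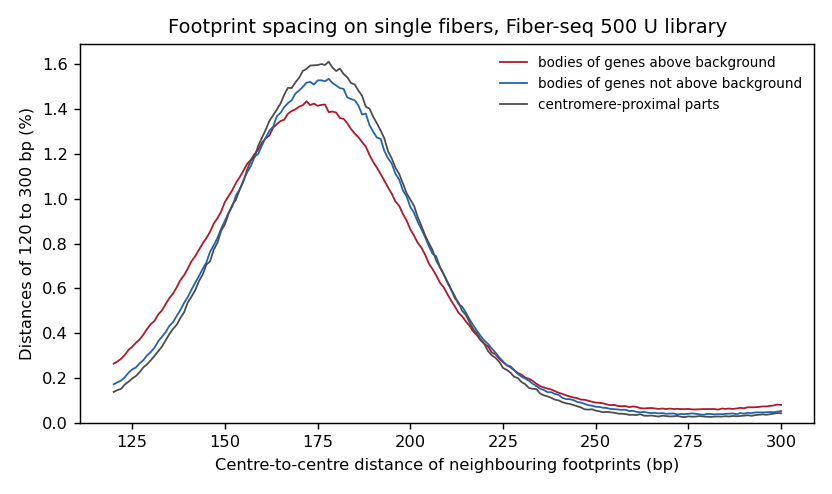
Share of centre-to-centre distances of neighbouring footprints (vertical axis, percent) by distance in bp (horizontal axis) in the 500 U library, by region as the legend names. The curve for bodies of genes above background is lower and broader, with a median of 176 bp against 178 bp in other gene bodies.

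Open gene ends that share a fiber were open together more often than chance within fibers of similar m6A. For 237 pairs of ends 0.5 to 1 kb apart the odds ratio was 1.88 (95% interval 1.70 to 2.06), with both ends open in 5888 of 11621 observations of a pair on a fiber against 5628 by chance. It was 1.61 (1.49 to 1.74) for 607 pairs at 1 to 2 kb, 1.42 (1.35 to 1.48) for 1477 pairs at 2 to 5 kb and 1.43 (1.33 to 1.54) for 448 pairs at 5 to 10 kb, where both were open in 7154 of 16442 such observations against 6929 by chance. The permutation p was 0.0099 at each distance, the smallest that 100 permutations allow. Random windows away from gene ends had odds ratios of 2.23, 1.72, 1.33 and 1.18 at the same distances, so at short range gene ends did not exceed random windows. The random windows were not chosen to be above background and were open less often. At 0.5 to 1 kb both were open in 60647 of 267809 observations. With sites at least 500 bp apart the odds ratio at 5 to 10 kb was 1.30 (1.17 to 1.43) for 250 pairs, an interval that overlaps that of the 1154 random pairs at this distance (1.10 to 1.25). Of 2769 single pairs, 3 passed the threshold in an exact stratified test, all open together more often than chance. Both pairs of His2A:CG33856 and of His2B:CG33874 with His4:CG33873 lie in the repeated histone array. The third was CG31926 with CG18131, on 2L at 1497071 and 1498455, with 27 of 57 fibers open at both against 19.3 by chance (exact stratified test, adjusted p = 0.0148). The next pairs in order, CG31661 with CG18131 and the ends of CG32235, did not pass (adjusted p of 0.131 and 0.161). At an unadjusted p under 0.05 there were 109 pairs (3.94%), 108 of them with more joint opening than chance. Of these 109 pairs, 33 were among the 146 pairs with a histone gene of the repeated array.

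**Figure D4:**
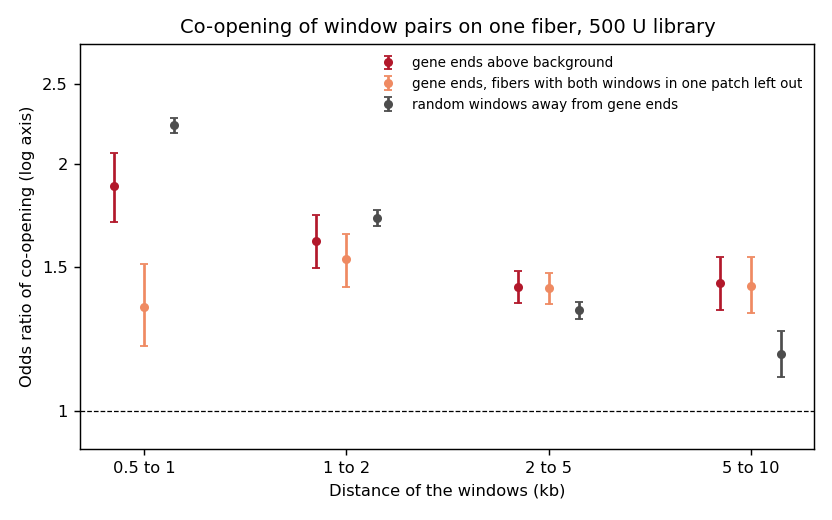
Odds ratio of 2 windows being open on the same fiber (vertical axis, log scale) by their distance in kb (horizontal axis) in the 500 U library, for gene ends and for random windows away from gene ends. Points are odds ratios and bars are 95% intervals from resampled pairs. The points of gene ends lie above those of random windows only at the distances from 2 kb upward. At 2 to 5 kb the intervals overlap slightly (1.354 to 1.482 for gene ends, 1.297 to 1.356 for random windows).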

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

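The tests on the score, the test without the lowest bins and those with sites at least 500 bp apart were chosen only after the result was seen, as was the limit of 30 calls per kb for mitochondrial fibers, and no biological explanation was tested, since the design has 1 library with m6A calls and no groups to compare.

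Mitochondrial DNA, which no comparison of genes uses, gave a signal of its own. Of 374 mitochondrial fibers, 50 (13.4%, exact 95% interval 10.1% to 17.2%) carried over 30 calls per kb, while the median mitochondrial fiber had 3.45. On the arms and chromosome 4, 94.7% of fibers were over this limit. Among mitochondrial fibers of at least 5 kb it was 7 of 238 (2.94%). No m6A calls of a control library were used here, so the false calls behind these values are unknown.

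Co-opening of gene ends 5 to 10 kb apart exceeded that of random windows, with an odds ratio of 1.43 (95% interval 1.33 to 1.54) against 1.15 (1.13 to 1.18) in a larger set of 12565 random pairs drawn for these tests and 1.18 (1.10 to 1.25) in the 1154 random pairs of the main comparison. With sites at least 500 bp apart it was 1.30 (1.17 to 1.43), an interval that overlaps the smaller random set and starts at 1.17 or 1.18, by the draw of the resampling, beside the upper bound of the larger set. These pairs can still share gene ends and fibers, so this interval too may be too narrow. Remaining differences between fibers in m6A and score might cause the excess. With 40 strata of both, the odds ratio was 1.34 (1.20 to 1.51) at gene ends and 1.05 (1.02 to 1.08) at random windows. For sites at least 500 bp apart it was 1.24 with a lower bound of 1.09. Pairs at all distances had a median of 30 fibers, so many strata held at most 1 fiber and pairs with many fibers weighed most. The histone genes were not left out under these strata, so the values do not settle this explanation. Fibers placed wrongly in the repeated histone genes are argued against, since without these genes the odds ratio was 1.46 (1.30 to 1.64). With sites also at least 500 bp apart it was 1.38 (1.19 to 1.60) for 222 pairs. That interval lies above the larger random set but overlaps the smaller one. The higher open share of gene ends stays open and cannot be told apart from a joint state of the ends, since random windows with shares of 40% to 90% reached 1.25 (1.21 to 1.29), below all gene ends but inside the interval for sites at least 500 bp apart.

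The m6A rate of a fiber was higher at high scores, with a median of 46.3 calls per kb at a score of 10 and 157 at scores of 51 and more, but it did not rise at each step (69.3 at 12 and 65.0 at 13, 72.9 at 14 to 15 and 69.9 at 16 to 20). Fiber length could explain this, as fibers of high score are shorter, but among fibers of 8 to 12 kb the rate at scores of 16 to 20 was still 1.53 times that at a score of 10 (70.8 against 46.3 per kb). An origin in more open DNA is argued against too, since over the same 1 kb bins the rate was 1.51 times that at a score of 10 for these fibers (SD over 5 arms 0.00905) and 3.31 times for scores of 51 and more of any length (SD 0.0328). Length stays open for the highest scores, whose fibers have a median of 1520 bp, as does how the score was made.

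Centromere-proximal sequence had fewer m6A calls than distal sequence, by -1.69 per kb. Lower scores of proximal fibers are argued against, since at the same score distribution the difference was -1.79 per kb (SD over 5 arms 1.06). A few loci with poorly methylated fibers could carry it, such as 3L from 24610001 to 24630000 with 1.75 and 1.40 calls per kb at coverages of 402 and 482. Without the lowest 5% of 10 kb bins in each part the difference was -1.04 (SD 0.600, lower on 5 of 5 arms). Such loci and a broad difference cannot be told apart, since the value without the lowest bins did not clear the limit set for the test by its SD.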

How the results depend on the processing

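The tests with a 60 bp gap, with fibers of at least the median score, with each side of the chip, with lists matched on gene length, with genes lacking a neighbour within 1 kb, with strata of score, with one-patch fibers left out, with sites 500 bp apart and without the histone genes were chosen only after the result was seen, as was the trimmed proximal difference. Of the values of single named genes under all alternatives, 606 kept their side of the threshold and direction, 26 lost their call and 10 gained one. Of the summary values, 337 kept theirs, 50 moved, 17 lost their call, 4 gained one and 3 reversed. No paired analysis was possible because each condition has 1 library. The most 5 prime start, m6A per A/T base, A/T matching, core promoter elements and a split by sequencing run were planned and not run, since sequence, strand and run names were not used here. The cause of the changes below was not tested, except where fewer fibers or genes entered by construction. At 40 fibers, the median, the simulation missed part of the genes with 70% against 40% open (72.5% were called), so smaller differences can be missed in single genes.

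With fibers of at least 5 kb, m6A was 60.3 per kb, the 20 U library kept 5 fibers, the one labelled deproteinized DNA kept 1 and that labelled genomic DNA 206454, and the ratio of fiber ends was 1.14 with 500 U and 1.18 in the library labelled genomic DNA. Without the extreme 10% of fibers by m6A, m6A was 63.0 per kb, the proximal difference -0.043, the percentile of mitochondrial respiration 91.6, the footprint length 111 bp and the first minimum inside genes 56.1 per kb. With fibers of at least the median score, m6A was 68.2 per kb, the profile maximum 104 and its minimum 61.7. There, 2269 genes were above background and 52 below of 5226 tested, the median share was 59.1%, patches measured 496 bp, and 2 lists passed the upper limit. The percentiles were 88.1 for mitochondrial respiration, 97.0 for the proteasome and 7.59 for testis.

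A gap of 60 bp gave a median share of 40%, patches of 268 bp, footprints of 100 bp and centre distances with a median of 179 bp and a mode of 177 bp. A gap of 75 bp gave 53.8%, patches of 347 bp, footprints of 107 bp and distances of 178 and 176 bp. A gap of 100 bp gave 75.6%, patches of 841 bp, footprints with a median of 121 bp and a mode of 104 bp, and distances of 176 and 174 bp. Under that gap the percentiles were 97.3 for mitochondrial respiration, 1.56 for neuronal and 4.02 for testis genes. By construction a larger gap removes short footprints and joins patches. With patches of at least 120 bp their width was 447 bp, and with at least 200 bp it was 511 bp, with a median share of 56.8% and percentiles of 83.7 for mitochondrial respiration, 98.4 for developmental transcription factors and 99.3 for the ecdysone response.

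With at least 40 fibers, 3377 of 6282 genes were above background, 2 lists passed the upper limit, and the percentiles were 93.9 for mitochondrial respiration, 95.9 for the proteasome and 11.8 for testis. The left side of the chip gave 2881 genes above and 50 below, 2 lists, and percentiles of 90.8, 93.9 and 9.55 for the same lists. The right side gave 2993 above and 45 below, 2 lists, and percentiles of 80.6, 88.4 and 16.9.

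Among genes with no end of another gene within 1 kb, 521 were above and 54 below with a median share of 46.5%, and of the 9 lists with enough such genes 2 passed the upper limit and 0 the lower. The proteasome, DNA replication and histone lists were not among the 9. The percentile turned to 32.1 for mitochondrial respiration, 68.0 for chemoreceptors and 55.5 for cuticle proteins, and was 100 for developmental transcription factors and 9.43 for testis.

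The co-opening odds ratios stayed above 1 in each alternative run, with the smallest possible permutation p except at 5 to 10 kb with fibers of at least the median score (odds ratio 1.42, permutation p = 0.0198). Without strata they were 2.31, 2.11, 1.89 and 1.82 from the shortest to the longest distance, and without fibers holding both ends in 1 patch 1.34, 1.53, 1.41 and 1.42.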

Other observations

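The sets in this part and their limits were chosen only after the result was seen. Genes for transfer RNAs, transcribed by RNA polymerase III, had the highest median share among the classes of noncoding genes, a difference that was not tested, since such genes often lie in clusters and share fibers. Of 265 tRNA genes tested, 189 (71.3%) were above background, with a median share of 75% (quartiles 56.2% and 87.5%). Among the 167 with no protein-coding gene end within 1 kb, 114 were above, with a median of 73.8%. For snRNA genes, of the splicing machinery, 14 of 27 were above with a median of 59.4%, but 5 of 14 with a median of 47.7% away from protein-coding gene ends. For microRNA genes it was 68 of 220 with a median of 53.4%, and 33 of 138 with 51.3% away from them. Antisense RNA genes had 199 of 460 above with a median of 56.6%, and 32 of 93 with a median of 48.8% away from protein-coding gene ends. For snoRNA genes, mostly lying in introns, 51 of 240 were above with a median of 46.4%, and 26 of 130 with 43.2% away from them. Long noncoding RNA genes (321 of 1767 above, 18.2%) and pseudogenes (45 of 184 above, 24.5%) had medians of 42.9% and 44.3%, near the background share of 41.1%. Away from protein-coding gene ends it was 150 of 1148 with a median of 40.9% and 18 of 64 with 42.3%.

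Open sites also lay far from any annotated gene end. Of 624563 windows at least 2 kb from gene ends, 13334 were open on at least 80% of fibers, where sampling of fibers at the background share would give 12. That reference holds the share equal at every window. Random windows vary more (15.1% called above background and 13.7% below), so an excess over 12 was given in advance and is not a test. The 13334 windows formed 5688 sites with a median length of 300 bp, and 4412 (77.6%) lay inside protein-coding genes, where 66.5% of the tested windows lie. In protein-coding genes, the sites open on every fiber with the most fibers were those in EcR, the ecdysone receptor gene (61 fibers, 2R from 6131801 to 6132400), in sick (57 fibers, 2L from 19887401 to 19887900), in sr, a transcription factor gene of tendon cells (57 fibers, 3R from 18121401 to 18122200), and in bin3 and Spn (53 fibers each). The genes with the most sites were long ones, namely Myo81F with 144, Pzl with 56, dpy, of the extracellular matrix, with 46, lovit with 34 and DIP-lambda with 29. Per 100 kb of gene these were 7.33, 7.89, 33.6, 7.83 and 7.65 sites. Transcription starts inside genes were not used here, so some of these sites are not necessarily distal to a start.

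No fiber had the same coordinates and hole number in more than 1 library (0 in each of the pairs compared). Matched also on gene length, the list percentiles were 99.97 for mitochondrial respiration, 1.41 for neuronal and 0.105 for cuticle protein genes, with 0 for chemoreceptors.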
